A study of Homo sapiens with 2 samples.

How the data were processed

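RNA from 2 samples of A549 cells was measured, 1 sample with an empty vector and 1 overexpressing miR-130b, each after immunoprecipitation with an anti-Ago2 antibody, per the labels. The labels state biotin labelling of whole-transcript cDNA for an Affymetrix array with 1 channel per sample. Their extraction protocol describes excised tissue and a kit for small RNA, although both samples are of a cell line, so how the precipitated RNA was purified stays uncertain. The deposited values are log2 expression values per probe set, with 33297 probe sets per sample. The unit was taken from the values, which run from 1.95 to 14.2: a natural or base-10 log of a 16-bit scanner value would end lower. The software, the background correction and the normalization behind the values are not given in the sources used here. The columns have nearly the same distribution (medians of 7.77 in both), which a quantile-type normalization gives. Such a normalization removes any overall difference in the amount of RNA precipitated, so each difference is relative to the other probe sets. The values were not centred per gene. The files give no detection p-values, so probes at background could not be marked. Array background adds to low signals, so folds with a low value on either array may be understated. Examples are MIR130B, NCKAP5, PPARGC1A, DMBT1, A1CF, NIBAN1, SPX, TRIM31 and ARFGEF3.

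Probe sets were named through a supplied copy of the platform annotation, which listed 21214 of them. Of these, 19460 had 1 gene symbol and 1754 had several, and 12083 probe sets were unnamed here. Symbols were updated through Entrez identifiers, which matched a current RefSeq gene for 19429 of the 19460 probe sets. Probe sets with several symbols were left out, so genes that share probes with a pseudogene or paralog (HSPA1A, RPL21) were not analysed as single genes. Several probe sets of a gene were averaged, which gave 18417 genes. Genes were kept if their mean over both arrays was at or above the median of all named genes (8.64), which left 9209. No coordinates are given because the files name no genome build.

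With 1 array per group, no test, standard error or p-value was computed. Each gene has the difference of its log2 values, and genes were counted at a threshold of 2-fold. For each gene list the median difference of its kept members was set against 10000 random lists of the same size, drawn with the same number of genes from each of 20 bins of mean expression. A list was called outside the random range if its median lay below the 2.5th or above the 97.5th percentile. Lists with fewer than 3 kept members have no percentile. There were 22 lists, fixed with their members before the data were examined and drawn from general knowledge of the field. The target lists were not checked against the literature, and some members may be predicted rather than tested targets. The list of mitochondrial transcripts had 0 members among the named probe sets and gave no value. Small non-coding RNAs were grouped by symbol. The genes named in the text follow a rule also fixed before the data were examined: TIMP2, AGO2 and MIR130B, the 12 largest increases and the 12 largest decreases among kept genes (without small RNAs, open reading frame symbols, pseudogenes and genes with shared probe sets), the 5 largest changes each way among reported miR-130b targets, and the 2 largest each way in every other list. A few other members were added as examples after their values were seen: PPARGC1A, E2F2, CDC20, MKI67, DLGAP5, CDK1, VIM, TIMP1, TIMP4, ADAM17, ASNS, CHAC1, HSPA5, ATF4, ZFP36, FOSL1, IER3, ATF3, COL1A1, ACTA2, FAP, LOX, DCN and LUM. The genes of the 5 lists in the closing section were also chosen after their values were seen.

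The list procedure was tested on simulated differences for the 9209 genes of this comparison, with normal noise of the robust SD of the real differences (0.29). Of 200 unchanged lists of 25 genes, 96.5% lay inside the random range. Unchanged and random lists were drawn from the same noise, so a share close to the coverage of that range was set by the design. Lists shifted by 0.1 were found above it in 24.0% of cases, lists shifted by 0.2 in 82.0% and lists shifted by 0.4 in 100.0%. Of 200 genes shifted by 1.5 on the log2 scale, 94.0% were counted as at least 2-fold higher. The simulated noise was normal and held no genes that move together. Real differences had wider tails, from -0.85 at the 2.5th percentile to 0.81 at the 97.5th. The simulated rates therefore need not hold for the real gene lists. The number of arrays limits the precision.

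The alternatives were no filter, a filter at the 75th percentile, centring on the median difference, quantile normalization and cyclic loess of the arrays, the brightest probe set per gene, a threshold of 1.5-fold, Spearman's rho and the mean of a list. The planned search for miR-130b seed matches in 3' untranslated regions was not run, because transcript sequences were not used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.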

Results

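The data were 2 microarray profiles of RNA that was pulled down with an antibody against Argonaute2 (Ago2) from A549 cells, an established human lung adenocarcinoma line. Ago2 is the protein that carries microRNAs and holds the mRNAs they pair with. One culture had been transfected with an empty vector and the other overexpressed miR-130b, and each group had 1 array. The comparison addressed which mRNAs were more abundant in the Ago2 precipitate when miR-130b was overexpressed. Each array held 33297 probe sets, with a median of 7.77 on the log2 scale in both groups. After naming and a filter on low values, 9209 genes entered the comparison. There were no replicates, so no value below has a replicate error or a p-value. Differences are log2 values of the miR-130b array minus the empty-vector array, and they describe these 2 arrays. Where 1 gene had several different probe sets, the difference varied between them with a pooled SD of 0.16 (356 genes), and 70.4% of the kept genes differed between the arrays by less than 2 such SDs. That SD covers disagreement between probes within these arrays and leaves out variation between cultures and precipitations. No array of the RNA before precipitation was analysed here, so a difference combines a change in the amount of an mRNA with a change in its share bound to Ago2. No array of a control precipitate without the Ago2 antibody was analysed either. RNA carried over without binding to Ago2 can therefore be part of any value.

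The probe set of the overexpressed microRNA's own gene separated the arrays as the labels state. MIR130B stood at 6.66 in the empty-vector array and at 12.64 in the miR-130b array, a 63.3-fold difference and the largest increase among all kept genes. The probe set covers the microRNA's gene and need not measure the mature microRNA. The mRNA of Ago2 itself, AGO2, differed by 0.25 (1.19-fold), from 11.41 to 11.66. TIMP2, which encodes an inhibitor of matrix metalloproteinases and has been reported as a miR-130b target, was abundant on both arrays, at 12.40 with the empty vector and 12.54 with miR-130b. Its difference of 0.14 (1.10-fold) lay at the 68.2nd percentile of the kept genes and was smaller than the SD between probe sets of 1 gene.

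Across the kept genes, 122 (1.32%) were at least 2-fold higher with miR-130b and 147 (1.60%) were at least 2-fold lower. The arrays correlated with a Pearson's r of 0.939 across genes, which are not independent replicates, and the median difference was 0.010. The counts changed with the filter on low values and the number of genes it left, with 196 higher and 252 lower of 18417 genes without a filter. They were 40 higher and 60 lower of 4605 genes with the filter at the 75th percentile of expression.

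The 12 genes with the largest increases, leaving out small RNAs, were between 3.25-fold and 18.0-fold higher with miR-130b. MMP2, the gelatinase that degrades type IV collagen, was 10.1-fold higher (8.72 against 12.05). HAS2, a hyaluronan synthase, was 5.30-fold higher, and SPARC, a collagen-binding matrix glycoprotein, was 5.04-fold higher. HMCN1, which encodes the matrix protein hemicentin, was 4.37-fold higher, and SFRP1, a secreted Wnt antagonist, was 3.25-fold higher. The largest increase after MIR130B was that of NCKAP5, which was 18.0-fold higher (7.24 against 11.41). HSPA2, an HSP70-family chaperone, was 10.6-fold higher. DMBT1, a secreted scavenger-receptor glycoprotein, was 8.61-fold higher. NR4A2, an orphan nuclear receptor, was 5.42-fold higher, FAM111B 5.40-fold, LYPD1 4.56-fold and the signalling adaptor SHC3 3.64-fold.

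**Figure D1:**
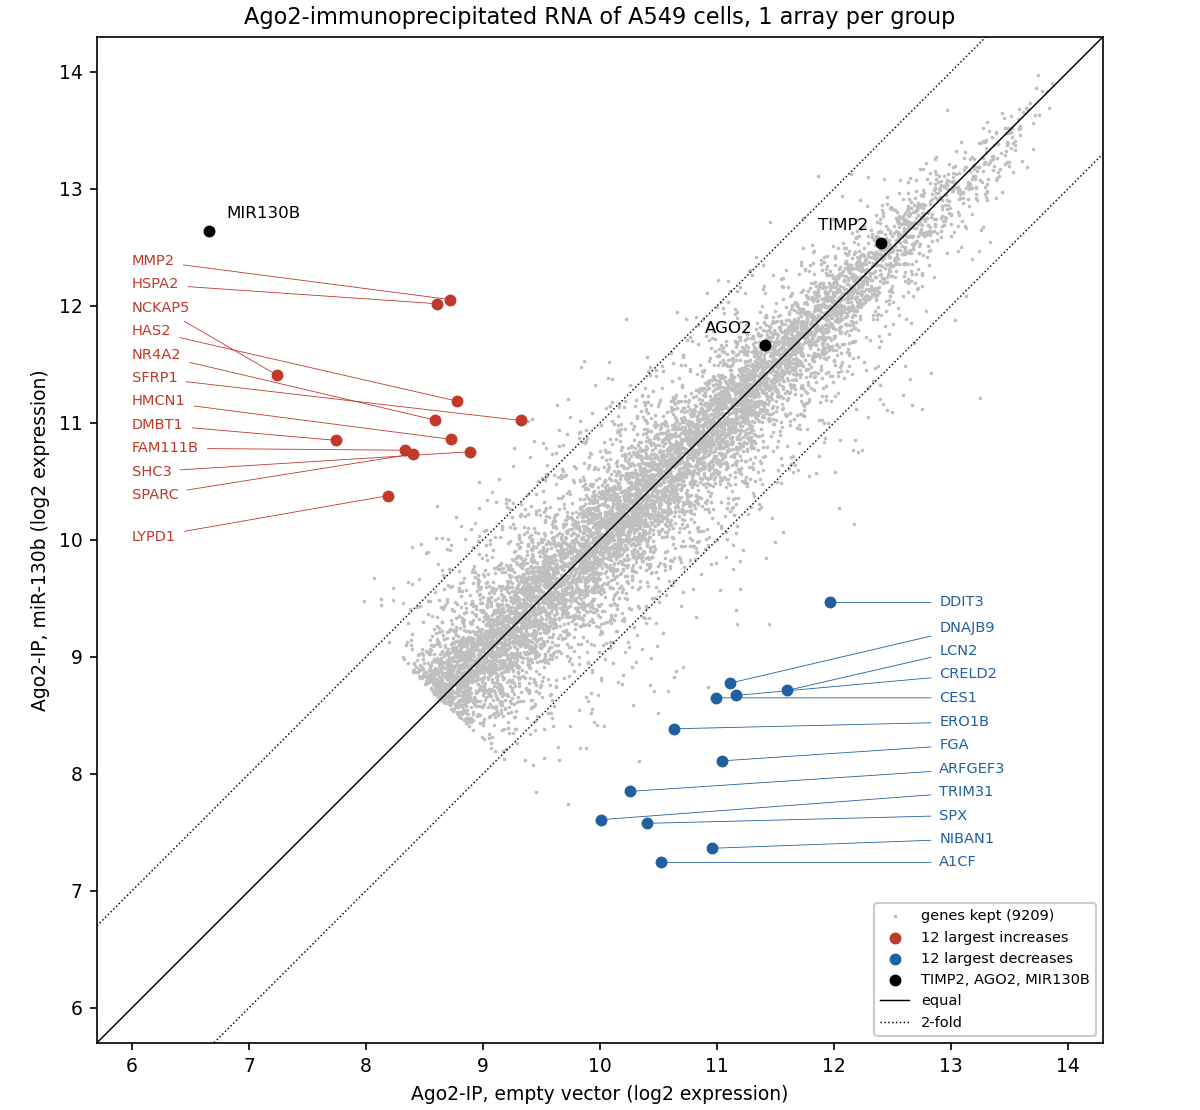
Log2 expression of each of 9209 kept genes in the Ago2 precipitate with empty vector (x axis) and with miR-130b (y axis), 1 array each, with the 12 largest increases in red, the 12 largest decreases in blue and 3 genes fixed in advance in black. MIR130B lies far above the line of equality at 6.66 and 12.64, while TIMP2 (12.40 and 12.54) and AGO2 (11.41 and 11.66) lie close to it.

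The 12 genes with the largest decreases differed by between -2.25 and -3.59. DDIT3, the stress-induced transcription factor CHOP, was 5.65-fold lower with miR-130b (11.96 against 9.47). CRELD2, an endoplasmic reticulum stress-inducible protein, was 5.64-fold lower. DNAJB9, a co-chaperone of BiP, was 5.04-fold lower, and ERO1B, an oxidase that drives disulphide formation, was 4.76-fold lower. NIBAN1, a stress-inducible gene, had the largest decrease among kept genes (10.95 against 7.36). FGA, the fibrinogen alpha chain, was 7.62-fold lower and LCN2, a siderophore-binding lipocalin, 7.41-fold lower. A1CF, the APOBEC1 complementation factor, was 9.73-fold lower, SPX 7.07-fold, ARFGEF3 5.32-fold, the ubiquitin ligase TRIM31 5.28-fold and the carboxylesterase CES1 5.08-fold.

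Genes reported as targets of miR-130b or of microRNAs with the same seed were slightly higher as a group. The list was compiled from general knowledge without a check of the literature, so it can hold predicted targets. Of 55 listed genes, 50 were measured and 41 passed the filter, of which 27 were higher and 14 lower, with a median difference of 0.14. That median lay above 99.6% of 10000 random lists matched on expression, whose central 95% ran from -0.099 to 0.10. MMP2 was the 1 kept member at least 2-fold higher, and none was at least 2-fold lower. The next largest increases were those of BCL2L11, a pro-apoptotic BH3-only gene, at 0.97, TP53INP1, a p53-induced gene, at 0.92, CCNA2, cyclin A2, at 0.91 and RPS6KA5, a kinase, at 0.62. The largest decreases among kept members were those of the transcription factors RUNX3 (-0.79), KLF4 (-0.79) and PPARG (-0.74), of RAB5A (-0.53) and of the deubiquitinase CYLD (-0.34). PPARGC1A, below the filter on mean level and named after its values were seen, stood at 10.07 with the empty vector and 6.33 with miR-130b, a difference of -3.74. Its lower value lies near the level of olfactory receptor genes (median 5.86). E2F2, also below the filter and named after its values were seen, was 2.02-fold higher. The list shared 22 genes with the other lists. The 21 kept targets found in no other list had a median of -0.073 at the 15.6th percentile of random lists, so the shift of the full list was not present in them.

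Targets of 4 other microRNA families were measured in the same way. The miR-21 target list had a median of 0.30 (14 kept, 99.9th percentile), with SPRY2, an inhibitor of receptor tyrosine kinase signalling, at 0.80 and RECK, a membrane-anchored protease inhibitor, at 0.63. Its lowest kept members were NFIB at -0.067 and PLEKHA1 at -0.0065. The lists of miR-200 targets (0.15, 17 kept), miR-17 family targets (0.085, 29 kept) and let-7 targets (0.059, 17 kept) lay inside the central 95% of random lists. The miR-200 list was close to its edge and lay above it under 3 of 7 alternative settings, and the mean of the miR-17 list, 0.15, lay above the range. Within them FHOD1 differed by 0.90, E2F1 by 0.73, THBS1, which encodes thrombospondin 1, by 1.26 and CDC25A by 0.91. FN1, fibronectin, differed by -0.47, JAG1 by -0.39, CDKN1A by -0.35, ARHGAP12 by -0.34, IGF2BP2 by -0.85 and E2F5 by -0.46. The 34 kept miR-130b targets that were in none of these 4 lists had a median of 0.026, and the 67 kept targets of the other microRNAs that were not in the miR-130b list had a median of 0.068. The seed of the miR-17 family shares 5 bases with that of miR-130b, so these other targets are not all of unrelated seeds. The difference between these medians was -0.042, inside the range of -0.13 to 0.15 that held 95% of 10000 reshufflings of the genes. The 27 kept mRNAs of the microRNA pathway had a median of 0.11, inside the random range, with DCP2 at 0.46, CNOT8 at 0.38, PAN2 at -0.52 and PRKRA at -0.29.

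**Figure D2:**
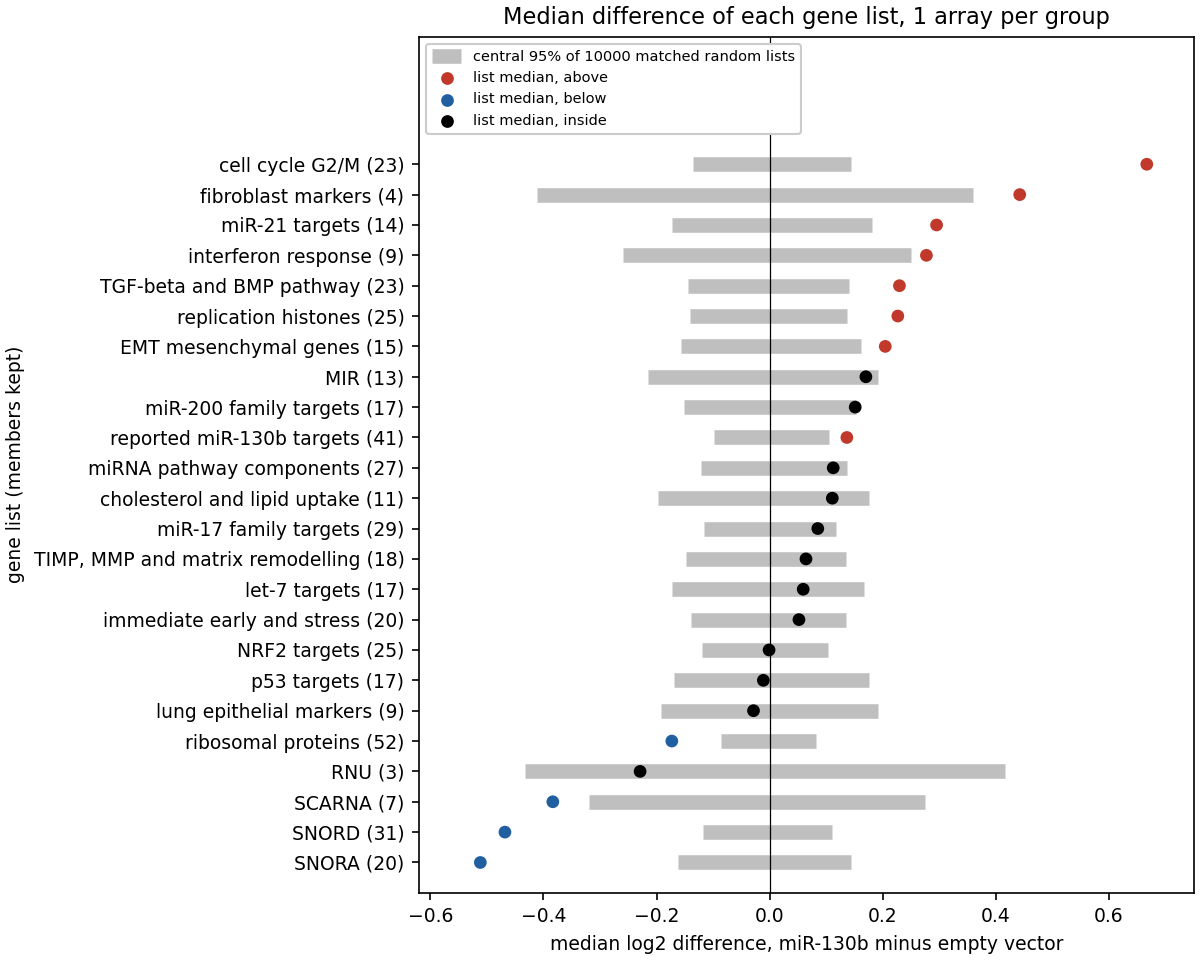
Median log2 difference (miR-130b minus empty vector, x axis) of the gene lists fixed in advance and of the small-RNA classes (y axis). Lists and classes with at least 3 kept members are shown, with the number kept in brackets. The grey bar marks the central 95% of 10000 random lists of the same size and expression. The cell cycle list lies farthest to the right at 0.67, the small nucleolar RNA classes farthest to the left at -0.47 and -0.51, and the reported miR-130b targets lie at 0.14.

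Of the fixed lists with a percentile, that of G2 and mitosis genes had the largest median. All 23 kept genes of the G2 and mitosis list were higher with miR-130b, with a median of 0.67, above all 10000 random lists. CENPE, a kinetochore motor, was 2.33-fold higher and CENPF 2.12-fold higher. The other members at least 2-fold higher were DLGAP5 (1.07), MKI67 (1.02), which encodes the proliferation antigen Ki-67, and CDK1 (9.55 against 10.55). The smallest increase among kept members was that of CDC20, at 0.12. Replication-dependent histone mRNAs were higher in 22 of 25 kept members, with a median of 0.23 at the 99.9th percentile. H1-5 differed by 1.12 and H2AC4 by 0.98, while H4C8 differed by -0.32 and H4C3 by -0.25. With the filter at the 75th percentile the histone median was 0.087, inside the random range. Near-identical histone copies share probes, so single histone values are uncertain.

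Ribosomal protein mRNAs and small nucleolar RNAs were lower. Of 52 kept ribosomal protein genes, 51 were lower with miR-130b and 1, RPL27A, was higher (0.19), while 47 were lower after quantile normalization and 48 after cyclic loess. Their median of -0.17 lay below all 10000 random lists, and RPL10A and RPS7 had the largest decreases, both at -0.57. The list median lay between -0.21 and -0.15 under the 7 alternative settings. All 31 kept C/D-box small nucleolar RNAs, 1 of them a pseudogene, were lower, with a median of -0.47, as were all 20 kept H/ACA-box RNAs, with a median of -0.51. The 7 kept Cajal-body RNAs had a median of -0.38 at the 1.16th percentile, and the 3 kept spliceosomal RNAs had a median of -0.23, inside the random range, although the median of all 15 measured genes with such symbols, a few of them small nucleolar RNAs or pseudogenes, lay at the 0.01st percentile when no filter was applied. Of 2 measured 7SL RNA pseudogenes, the 1 kept was at 0.27, and the median of both was 0.22. The 13 kept genes with microRNA symbols, MIR130B and some host genes included, had a median of 0.17, inside the range. The 361 olfactory receptor genes, which A549 cells are not expected to express, were all below the filter and had a median difference of 0.072.

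**Figure D3:**
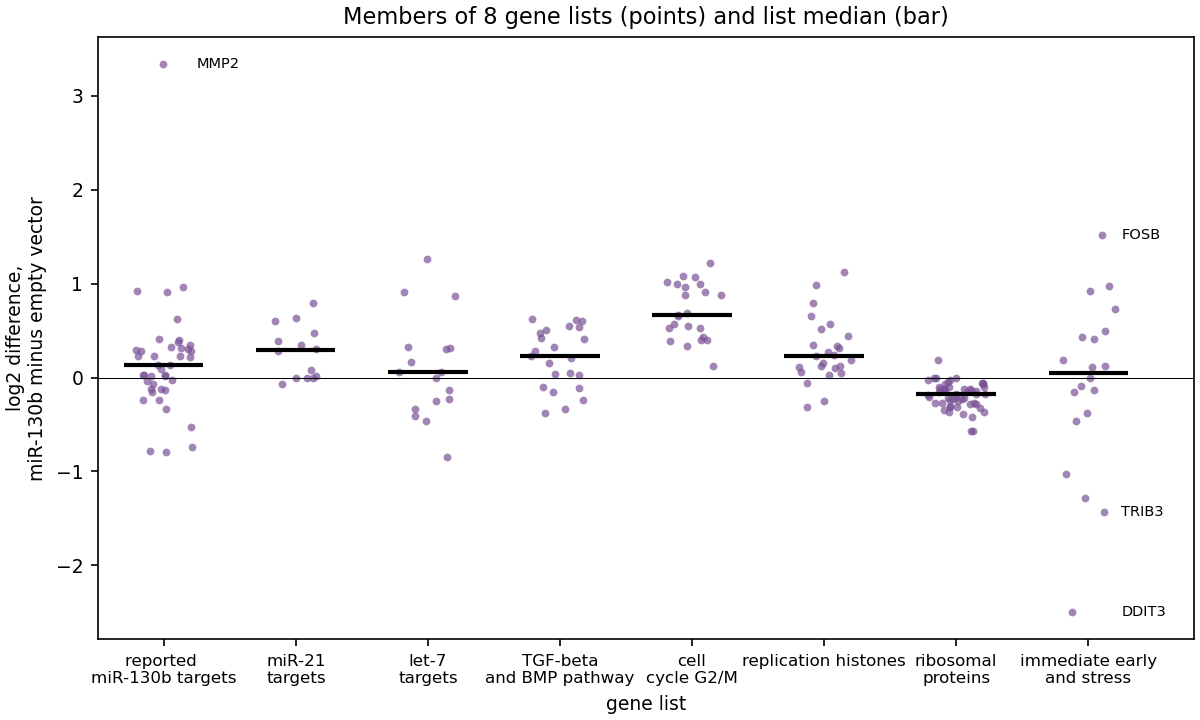
Log2 difference (miR-130b minus empty vector, y axis) of every kept member (points) of 8 gene lists (x axis), with the list median as a bar. The cell cycle genes all lie above 0, the ribosomal protein genes lie just below 0 except for 1 (5 after quantile normalization), and the stress list spreads from DDIT3 at -2.50 to FOSB at 1.51.

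A list of TGF-beta and BMP pathway genes, with receptors, SMADs, ligands, co-repressors and ubiquitin ligases, had a median of 0.23 (23 kept, 17 higher and 6 lower), at the 99.95th percentile. Of its 27 listed genes, 9 were also in other lists, among them reported miR-130b targets such as TGFBR1 and some miR-21 targets. Its median is therefore not independent of those lists. BAMBI, a pseudoreceptor, differed by 0.62 and SMAD2 by 0.61, whereas SMAD1 differed by -0.38 and ACVR2A by -0.33. The mesenchymal list had a median of 0.20 (15 kept, 99.6th percentile) and its members were unequal. SPARC and TNC, which encodes tenascin C, were 5.04-fold and 2.68-fold higher, FN1 was at -0.47, CCN1 at -0.20 and VIM, vimentin, at 0.052. The median of this list lay inside the random range with the filter at the 75th percentile (0.052) and with the brightest probe set per gene (0.13). Among lung epithelial markers, CDH1, E-cadherin, was 2.17-fold lower (12.61 against 11.49) and the lamellar-body transporter ABCA3 2.05-fold lower, while MUC1 was at 0.42 and KRT19 at 0.37. The epithelial list's median of -0.029 (9 kept) lay inside the random range, whereas its mean of -0.27 lay at the 1.06th percentile. Of the fibroblast markers, listed as another cell type, 4 of 15 passed the filter, with a median of 0.44 at the 99.0th percentile. They were COL5A1 at 0.95, FBN1 at 0.57, COL1A1 at 0.32 and ACTA2 at 0.0034, and FBN1 was the 1 left with the filter at the 75th percentile. Without a filter, all 15 measured markers, 11 of them below it, had a median of 0.33 at the 99.98th percentile. Below the filter, LOX was 2.60-fold lower (8.79 against 7.41). FAP stood at 5.26 with the empty vector, under the median of olfactory receptor genes on that array (5.77), and at 6.97 with miR-130b, so no fold is given. The abundant fibroblast transcripts DCN (4.46 with the empty vector, 4.55 with miR-130b) and LUM (7.21 and 7.68) were below the filter. Of 14 measured leukocyte markers 12 were below the filter, with CD68 at -1.18 and CD14 at 0.63 above it, and of 10 endothelial markers CLDN5, at 0.10, passed it.

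Within the metalloproteinase list, MMP2 stood apart from its relatives. The list median was 0.064 (18 kept, 11 higher and 7 lower), inside the random range. RECK was at 0.63, PLAU, the urokinase-type plasminogen activator, was 2.42-fold lower (12.65 against 11.38) and MMP7, matrilysin, was 1.91-fold lower. TIMP1 was at 0.097, ADAM17 at -0.71 and TIMP4 at -0.82.

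Members of the immediate early and stress list went both ways. The list median was 0.052 (20 kept, 10 higher and 10 lower), inside the random range, and its mean was -0.078. These values leave out the listed genes HSPA1A and HSPA1B, whose shared probe sets had a median difference of 1.86. Besides DDIT3, the members at least 2-fold lower were TRIB3 (-1.43) and CHAC1 (-1.02), which DDIT3 and ATF4 induce, and ASNS (-1.28), asparagine synthetase. HSPA5, the chaperone BiP, was at -0.47 and ATF4 at -0.37. The immediate early genes FOSB and FOS were 2.86-fold and 1.97-fold higher, and ZFP36 was at 0.93, while FOSL1 was at -0.13, IER3 at -0.16 and ATF3 at -0.095. Interferon-stimulated genes had a median of 0.28 (9 of 27 measured kept, 98.6th percentile), with OAS1 at 0.93, OAS3 at 0.72, USP18 at -0.33 and DDX60 at -0.088. With the filter at the 75th percentile, OAS3 was the 1 member left and the list had no percentile.

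The lists of p53 targets (-0.011, 17 kept), NRF2 targets (-0.0010, 25 kept) and cholesterol genes (0.11, 11 kept) lay inside the random range. In them SESN2, a stress-induced sestrin, was 2.65-fold lower, GADD45A was at -0.69 and SESN1 at 0.52. ALDH3A1, an aldehyde dehydrogenase, was at 0.68, AKR1C3 at 0.40, ABCC3 at -0.51 and GPX2 at -0.35. INSIG1, a sterol-regulated gene, was at 0.77, LRP8 at 0.38, VLDLR at -0.24 and DHCR7 at -0.18. Of the 19 fixed lists with at least 3 kept members, 8 lay above and 1 below the central 95% of random lists. By chance, 0.95 in all would lie outside if the genes of each list behaved like genes drawn at random. Genes of a list can move together without any treatment, so these percentiles describe the 2 arrays and do not compare conditions.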

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

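The flags below concern probe sets outside the gene-level comparison, and they were looked at only after the gene-level values had been seen. Among 825 probe sets with several gene symbols at or above the filter, 6 were at least 2-fold higher with miR-130b and 11 at least 2-fold lower, and the higher ones were flagged because no gene-level result covers them. Of these 6, 5 carry the paired symbols of HSPA1A and HSPA1B, the stress-inducible HSP70 genes, whose near-identical sequences share probes. Those 5 probe sets hold 4 distinct pairs of values, with a median difference of 1.86 (3.63-fold higher) and a range from 1.73 to 1.97. On the lower side, the probe set shared by OCLN, the tight junction gene occludin, and its pseudogene was 5.44-fold lower. Among 2487 unnamed probe sets at or above the filter, 5 were at least 2-fold higher and 31 at least 2-fold lower. No explanation for these was tested.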

How the results depend on the processing

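Each result was recomputed under the alternatives fixed before the data were examined; the settings that changed the members of the miR-130b target list were chosen after seeing the data. Under centring, quantile normalization, cyclic loess and the brightest probe set, every count stayed within 1.5 times its value and every list median within the SD of its random lists, but with the brightest probe set the mesenchymal median of 0.13 lay inside the random range, which ended its call, and the miR-200 median lay just above it there and under quantile normalization and cyclic loess. MIR130B and TIMP2 also stayed within the SD between probe sets. Without a filter there were 196 higher and 252 lower genes, the correlation was 0.985, the miR-21 median was 0.18 and the leukocyte median 0.049. With the filter at the 75th percentile there were 40 higher and 60 lower genes, the correlation was 0.894, and the medians were 0.23 for reported miR-130b targets, 0.087 for histones, -0.16 for lung epithelial markers, -1.18 for leukocyte markers, 0.72 for interferon genes, -0.14 for p53 targets and 0.052 for mesenchymal genes; the calls of histones and mesenchymal genes ended there, with fewer members kept, and interferon, fibroblast and leukocyte markers had 1 member each (OAS3, FBN1 and CD68) and no percentile; the Cajal-body RNAs had none either. Spearman's rho was 0.935. At 1.5-fold there were 464 higher and 541 lower genes. With the mean in place of the median, miR-17 targets stood at 0.15, lung epithelial markers at -0.27, mesenchymal genes at 0.35 and the stress list at -0.078. Without members of other lists, the median of reported miR-130b targets reversed to -0.073. It was 0.026 without members of other microRNA lists and 0.11 without MMP2. These settings cannot tell the cause of the increase. Leaving out a replicate was not possible with 1 array per group. No paired analysis was possible because each group has 1 array and replicate numbers follow accession order. The seed-match and heptamer analyses were not run, since transcript sequences were not used here. The missing replicates and the unknown signal over background limit all values.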

Other observations

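The 5 gene lists and the tests in this part were chosen after the data were seen, including the comparisons of the miR-130b target list with other lists. The genes of protein folding and degradation in the endoplasmic reticulum were lower together with miR-130b. All 29 kept members of a list of 31 were lower (28 after quantile normalization or cyclic loess, with ERO1A the exception), 15 of them at least 2-fold, with a median of -1.06 (-0.93 without a filter and -0.76 with the filter at the 75th percentile). They included the folding factors SDF2L1 (-1.80) and HYOU1 (-1.40), the degradation factors HERPUD1 (-2.03) and SYVN1 (-1.32), and FICD (-2.04), which modifies the chaperone BiP. XBP1, a transcription factor of the unfolded protein response, was at -0.68, and ERO1A, at -0.0048, and CANX, calnexin, at -0.14, were the least changed. SDF2L1 is the nearest protein-coding gene on one side of MIR130B in the RefSeq annotation of GRCh38.p14, and it was lower while MIR130B was higher. Among genes that ATF4 induces in amino acid shortage and stress, 34 of 36 kept members were lower, 11 of them at least 2-fold, with a median of -0.50. NUPR1 (-1.87), ALDH1L2 (-1.58), STC2 (2.82-fold lower) and PCK2 (-1.46) were among them, while ATF5 was at 0.17 and DDIT4 at 0.11.

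Genes of DNA replication and the G1/S transition were higher, in 33 of 34 kept members, with a median of 0.80. E2F8 differed by 1.60, CLSPN by 1.42, CCNE1, cyclin E1, by 1.31, ORC1 by 1.29 and MCM10 by 1.29, and CDC6 was the exception at -0.33. Heat shock genes were higher in all 14 kept members, with a median of 0.34, among them HSPD1 at 0.12 and DNAJA1 at 0.57. HSPA2, at 3.41, was the 1 member at least 2-fold higher and is also among the 12 largest increases above. A list of acute phase and liver-type plasma proteins had 5 kept members, all lower, with a median of -2.18; without a filter its 18 members had a median of -0.076, and with the filter at the 75th percentile the value was -0.14, with no percentile. The kept members were FGA, LCN2, PTX3 (-2.18), CFB (-0.82) and C3 (-0.14), and FGB, the fibrinogen beta chain, was at -2.27 below the filter.

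The lower endoplasmic reticulum genes were weighed against 3 explanations. A trend of difference on level was argued against by random lists of the same level, which it would move alike and whose median was 0.0047. Lower recovery of all mRNAs translated at the endoplasmic reticulum was set against the matrix remodelling list, of secreted, membrane and lysosomal proteins. That list had a median of 0.064 from 18 kept members, so these mRNAs were not lower as a group. The endoplasmic reticulum list was chosen after its low values were seen, so a list not chosen that way would hardly reach its median. The comparison therefore cannot decide how much of a loss, if any, was common to all such mRNAs. Whether there were fewer of these mRNAs in the cells, not fewer bound to Ago2, cannot be told apart, since there were 0 input arrays. An effect of miR-130b itself and a difference between 2 single cultures were not tested.

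The lower ribosomal protein mRNAs and small nucleolar RNAs were weighed in the same way. A trend on level was argued against for the ribosomal protein list by random lists of the same level, whose median was 0.0036. A loss of short transcripts cannot be told apart: the short histone mRNAs had a median of 0.23, but proliferation genes were higher too, which could hide such a loss. Less carried-over RNA not bound to Ago2 may also be the cause and stays open, because the spliceosomal RNAs, which should follow it, had a median of -0.23 from 3 kept members, inside the random range, but all 15 genes with such symbols, most of them dim, lay below it, at -0.22, when no filter was applied. An effect of miR-130b itself was not tested.

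The small increase of reported miR-130b targets was weighed against what the list shares with others. Its members in no other list had a median of -0.073, so the increase lay in the shared members, such as CCNA2, BCL2L11 and TGFBR1. Shared members are in the miR-130b target list as well. The split therefore cannot tell an effect of miR-130b on them from a change of the other lists. It was not compared with random splits of the list. A like increase of the targets of other microRNAs cannot be told apart: the difference of the medians was -0.042, inside the reshuffled range, but the other targets lay at the 93.5th percentile of random lists and so did not stand apart either. Sites in the 3' untranslated regions were not searched, so an increase limited to mRNAs with a miR-130b site stays untested.

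Some genes at least 2-fold higher were neighbours. LYPD1 (2.19) lies next to NCKAP5 (4.17), HTRA1 (1.67) next to DMBT1 (3.11), LPCAT2 (1.22) next to MMP2 (3.34) and PTPRE (2.82-fold higher) next to MKI67 (1.02), in the order of kept genes. The 4 pairs compare with a mean of 1.61 in random gene sets of the same size and level, and 7.12% of 10000 such sets had as many. Among genes at least 2-fold lower there were 2 such pairs, ALG12 (-1.02) with CRELD2 (-2.50) and SEC24D (-1.19) with USP53 (-1.28), which were not compared with random sets.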
